A study of Mus musculus with 6 samples.

How the data were processed

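Cells were taken from the sagittal, coronal and lambdoid sutures of C57BL/6 mice, labelled male and wild type, in 4 digestion rounds of 20 min, and loaded as 1 library per group. The labels' protocols name 10x Genomics single cell 3' v3 chemistry, holes drilled 2 mm from the suture for the device, and a sham group with holes and no device. They do not state the time from surgery to harvest. The deposited files hold counts: unique molecular identifiers (UMIs) per gene and cell barcode, made by the authors with Cell Ranger 3.1.0 against mm10, with Partek named for later steps, per the submitters' processing notes. No cell names or cluster assignments were used from the authors, so all classes here were rebuilt from the counts, and differences from the study may come from that. The day 4 file lists 31053 gene identifiers and the other 5 list 32285, with 30406 in common. Of the rest, 647 were only in the day 4 file and 1879 were absent from it. Cells were clustered and compared on the shared identifiers, which held at least 99.6% of the UMIs of every library. Gene positions are from GENCODE M21 on mm10.

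Barcodes with at least 200 genes, at least 500 UMIs and at most 20% mitochondrial UMIs were kept. The mitochondrial limit removed 22.6% of barcodes at day 4, 15.4% at month 2, 3.06% in the sham library, 3.97% in the expanded library, 2.69% at month 4 and 3.00% at month 14. Scrublet scores ranked the remaining barcodes, and the highest were removed at 0.8% per 1000 barcodes, which took out 115, 109, 20, 126, 351 and 228 barcodes in that order. The threshold that Scrublet sets by itself called 5, 8, 2, 7, 12 and 13 and was not used. The kept cells numbered 3213, 3283, 1528, 3762, 6171 and 5013. Library totals were 33338440 UMIs at day 4, 32930943 at month 2, 22755401 in the sham library, 31655750 in the expanded library, 91063078 at month 4 and 52802622 at month 14. The median kept cell had 1648, 1472, 1798, 1532, 1891 and 1573 genes.

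Counts of all libraries were scaled per cell, log transformed, reduced to 2000 variable genes without cell cycle, dissociation and mitochondrial genes and to 30 principal components, joined to 15 neighbours and clustered with the Leiden method at resolution 1, with seed 1 and no batch correction. Clusters were named from marker lists of 21 cell classes, and those without a clear lead were left unnamed. The mesenchymal class joins the fibroblast-like and osteoblast-like or osteocyte-like classes. Prrx1, Postn, Tnn, Pi16, Cthrc1, Col3a1, Dpt and Clec3b are among the markers that name the fibroblast-like class. Clusters led by Ttr, Cxcl12 and Adgre4 were left unnamed by a rule set only after the clusters were seen. The Ttr cluster held 43 cells at month 2 (1.31%) and 5 in the sham library (0.327%). The Cxcl12 cluster, of stromal cells, held 0.335% of cells at month 2, 0.186% in the expanded library, 0.275% at month 4 and 0.160% at month 14. The Adgre4 cluster held 0.0311%, 0.822%, 1.05%, 0.106%, 0.713% and 0.578% of cells from day 4 to month 14 in the order above. All unnamed clusters together held 19.6% of cells at day 4, 7.95% at month 2, 6.02% in the sham library, 3.43% in the expanded library, 2.90% at month 4 and 2.25% at month 14. Classing each cell by its highest marker score gave 1578 mesenchymal cells against 1866 by cluster, of which 1420 were called by both.

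For cycling and Prrx1 shares each cell was thinned to 2000 UMIs, and cells below that depth were left out: 337 of the mesenchymal cells at day 4, 6 at month 2, 2 in the sham library, 2 in the expanded library, 0 at month 4 and 2 at month 14. A cell was called cycling with a UMI in at least 2 of 15 genes. T and NK cells served as the background class. Shares carry exact binomial (Clopper-Pearson) 95% intervals, and ratios of shares or levels carry exact intervals from the counts. All of them cover counting error only, since cells of 1 library are not replicates. A count of 0 was set to 3 counts for a bound, so a ratio against 0 is given as at least that size. No test between groups was run, and no count of changed genes was made.

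Gene levels are UMIs summed over the mesenchymal cells of a library, as counts per 1000000 UMIs (CPM), for genes with at least 20 UMIs in the 2 libraries compared. The comparisons were the expanded against the sham library with untreated month 2 beside it, the sham library against month 2, and day 4, month 4 and month 14 against month 2. Genes with at least 50 CPM in the higher library and a log2 ratio of at least 1 in size were ranked by the end of the interval nearest to 0, and the first 12 in each direction were selected, of which not every one is named in the text. A gene also had to differ by at least 1.5-fold the same way in a further comparison: from month 2 for expanded against sham, between the expanded and month 2 libraries for sham against month 2, from month 4 and month 14 for day 4, and from month 4 for month 14. Month 4 and the expanded library against month 2 had no such condition. Mitochondrial, ribosomal protein, haemoglobin, Y-linked, Gm and Rik genes and markers of other cell classes were left out of this ranking. Besides these, 14 genes were fixed, and 22 gene lists: skeletal stem and progenitor, osteogenic, chondrogenic, DNA replication, mitosis, the cycling call, collagens, matrix remodelling, the Wnt, BMP and TGF-beta, Hedgehog, and FGF and IGF pathways, YAP and TAZ targets, inflammatory cytokines, interferon response, hypoxia and glycolysis, dissociation stress, senescence, adipogenic, osteoclast regulators, vascular and nerve growth factors, and oxidative phosphorylation. A list is given by the median log2 ratio of its measured genes, with genes at 0 entered at their bound, and by the percentile of that median among 10000 random lists matched over 20 bins of expression. Examples are the members with the largest ratios at 20 CPM or more. Reads of Bglap, Bglap2 and Bglap3, of the Stfa and Cstdc genes, of the Hist1 family and of Xist and its antisense Tsix can be shared, so the split within each set is uncertain. The groups, comparisons, lists, rules and most of the alternative settings below were fixed before the data were examined.

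The gene step was run on simulated data with known changes, drawn as Poisson counts around a rate per gene shared by both libraries. The interval assumes such counts, so its coverage checks the calculation only. Differences between cells, mice or cell mixes were not simulated. For the expanded against the sham library the interval covered the true ratio for 96.3% of 10677 genes, and 66.0% of 97 genes changed 2-fold and 93.9% of 98 changed 4-fold were recovered. For day 4 against month 2 coverage was 96.7% of 12628 genes, with 46.9% of 98 and 81.4% of 97 recovered. Alternatives were at least 500 genes, at most 10% mitochondrial UMIs, no doublet removal, Leiden resolution 2, classes by marker score, shares of cells outside blood and immune classes, thinning to 1000 UMIs or none, at least 3 cycling genes, CPM without mitochondrial, ribosomal, haemoglobin and blood marker genes, median-of-ratios scaling, at least 100 UMIs, fibroblast-like cells alone, and the mean over cells. Chosen after seeing the data were counting the Cxcl12 cluster as mesenchymal, leaving out barcodes shared by month 4 and month 14, fibroblast-like cells alone for the cycling and Prrx1 ratios, month 2 as the reference, and all alternatives for osteoclast ratios. The tools were python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, anndata 0.12.19, leidenalg 0.10.2, igraph 0.11.9, scikit-learn 1.9.0 and matplotlib 3.10.9.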

Results

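Single-cell transcriptomes were collected from the cranial sutures of C57BL/6 mice, the fibrous joints between the flat bones of the skull vault that hold the stem and progenitor cells of those bones. The 6 libraries held 1 library per group, each pooled from several animals: day 4 (8 mice), month 2 (5 mice), month 2 after a sham operation with holes but no device (5 mice), month 2 after expansion of the sagittal suture with a nickel-titanium wire (6 mice), month 4 (5 mice) and month 14 (6 mice). The wire was 0.3 mm thick and pulled the bones apart with an initial force of 0.2 N. The 26130 cell barcodes carried between 22755401 unique molecular identifiers (UMIs, counted transcripts) in the sham library and 91063078 at month 4, and 22970 barcodes passed the cell filters. The median kept cell had 4632 UMIs at day 4, 4773 at month 2, 8580 in the sham library, 4449.5 in the expanded library, 8356 at month 4 and 5282 at month 14. No group had a replicate library, so no difference between groups had a replicate check. All intervals are exact 95% intervals of counting error only, and "higher" and "lower" describe these libraries.

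Blood and immune cells made up most of every library except that of day 4. Neutrophils held 45.4% to 61.3% of kept cells in the libraries from month 2 on and 4.73% at day 4. Mesenchymal cells, here fibroblast-like cells of the suture plus osteoblast-like or osteocyte-like cells, held 48.6% at day 4 (1563 of 3213 cells, interval 46.9% to 50.4%). They held 1.86% at month 2 (61 of 3283, 1.42% to 2.38%), 1.77% in the sham library (27 of 1528, 1.17% to 2.56%) and 5.29% in the expanded library (199 of 3762, 4.6% to 6.05%). At month 4 and month 14 they numbered 7 and 9 cells. Fibroblast-like cells came mainly from clusters 12 and 14 at day 4 and from cluster 27 in the expanded library, and osteoblast-like cells from cluster 17.

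**Figure D1:**
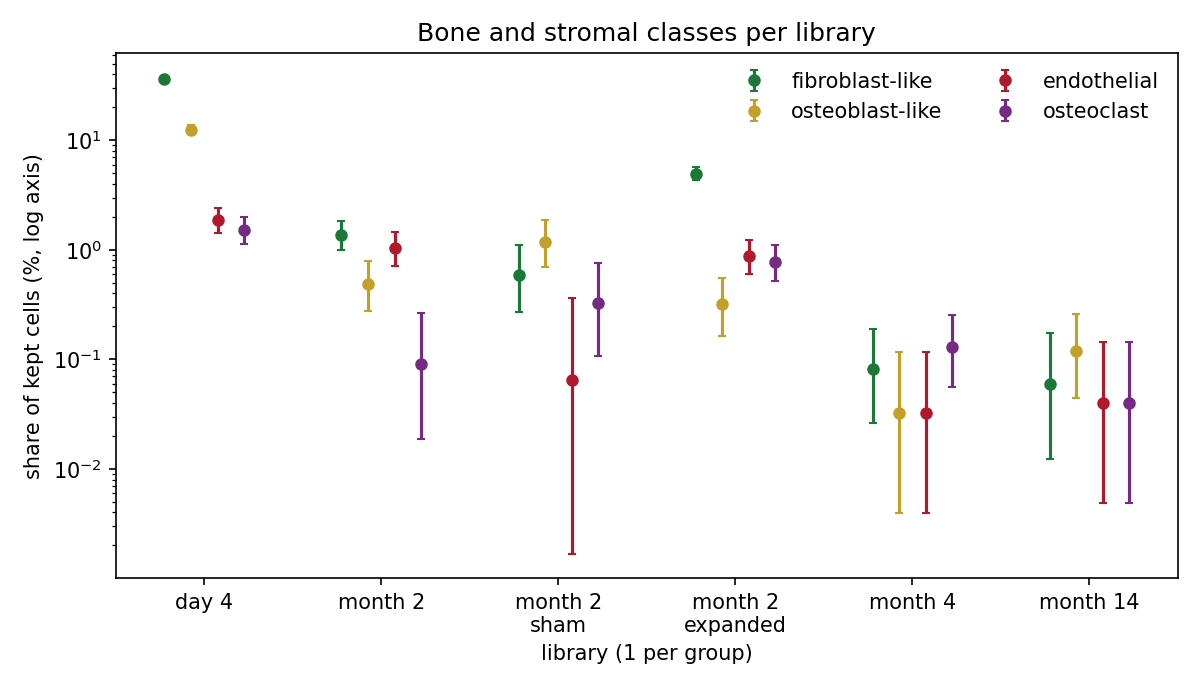
Share of kept cells (percent, log axis) of fibroblast-like, osteoblast-like, endothelial and osteoclast cells in each of the 6 libraries, with exact 95% binomial intervals as bars. In the expanded library fibroblast-like cells stood at 4.97% against 0.589% in the sham library, while osteoblast-like cells stood at 0.319% against 1.18%.

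Expansion against the sham operation asked how stretching the sagittal suture changes the skeletal cells of the sutures. Cells were taken from the sagittal, coronal and lambdoid sutures together, so those of the stretched suture were not told apart from the rest. Fibroblast-like cells made up 4.97% of the expanded library (187 cells), 0.589% of the sham library (9 cells) and 1.37% of the untreated month 2 library (45 cells), an expanded to sham ratio of 8.44 (4.35 to 18.7). Osteoblast-like cells went the other way, with 12 cells (0.319%) in the expanded and 18 (1.18%) in the sham library, a ratio of 0.271 (0.119 to 0.594). Together the mesenchymal share was 2.99-fold higher in the expanded library (2.00 to 4.66), and 2.85-fold higher than at untreated month 2 (2.13 to 3.86). Osteoclasts, the bone-resorbing cells, held 0.771% of the expanded library against 0.0914% at month 2, a ratio of 8.44 (2.61 to 43.3) that rests on 3 month 2 cells, and 0.327% in the sham library, a ratio of 2.36 (0.902 to 7.79). With doublets kept and cells clustered anew, 58, 20 and 14 osteoclasts in the expanded, month 2 and sham libraries gave ratios of 2.53 (1.499 to 4.44) and 1.65 (0.909 to 3.20). The cluster so named then held 272 cells at a median of 1734 UMIs, against 96 cells at 25782.5 UMIs before. It was thus not the same class, and these ratios do not show the effect of doublets alone. With cells classed by marker score the ratios were 5.07 (2.96 to 9.24) and 3.15 (1.72 to 6.31). Monocytes and macrophages held 10.8% of the expanded library, 5.89% of the sham and 6.73% of the month 2 library. Endothelial cells numbered 33 in the expanded library, 34 at month 2 and 1 in the sham library, and the sham library held 35 cells outside blood and immune classes in all. Among cells outside those classes, mesenchymal cells formed 63.0% of the expanded, 77.1% of the sham and 21.0% of the month 2 library, so that the expanded to sham ratio was 0.816 (0.544 to 1.27).

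Mesenchymal cells called cycling were seen in the expanded library and in neither month 2 reference after every cell had been thinned to 2000 UMIs. In the expanded library 52 of 197 mesenchymal cells (26.4%, 20.4% to 33.1%) carried transcripts of at least 2 of 15 genes of dividing cells. None of 25 did so in the sham library, which by the floor of 3 cells allows a share of up to 12.0% (exact upper limit 13.7%), and none of 55 at month 2, which allows 5.45% (6.49%). By that floor the expanded share was at least 2.20-fold above the sham share (lower end of the interval 1.73) and at least 4.84-fold above that of month 2 (3.80). All 52 cycling cells were fibroblast-like, 28.1% of the 185 such cells (21.8% to 35.2%), and none of 12 osteoblast-like cells was called. The sham library held only 7 fibroblast-like cells deep enough for the call, none of them cycling, which allows a share of up to 42.9%. Thinning left out 2 mesenchymal cells of the expanded library, 2 of the sham and 6 of the month 2 library, whose median depths were 21597, 30385 and 8060 UMIs. Without thinning the shares were 50.8% in the expanded, 29.6% in the sham and 8.20% in the month 2 library, and the expanded to sham ratio was 1.71 (0.837 to 4.08). T and NK cells, taken as the background class, were called at 4.76% in the expanded library (median depth 3517 UMIs), 16.7% in the sham library (7238.5 UMIs) and 9.41% at month 2 (3607 UMIs).

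**Figure D2:**
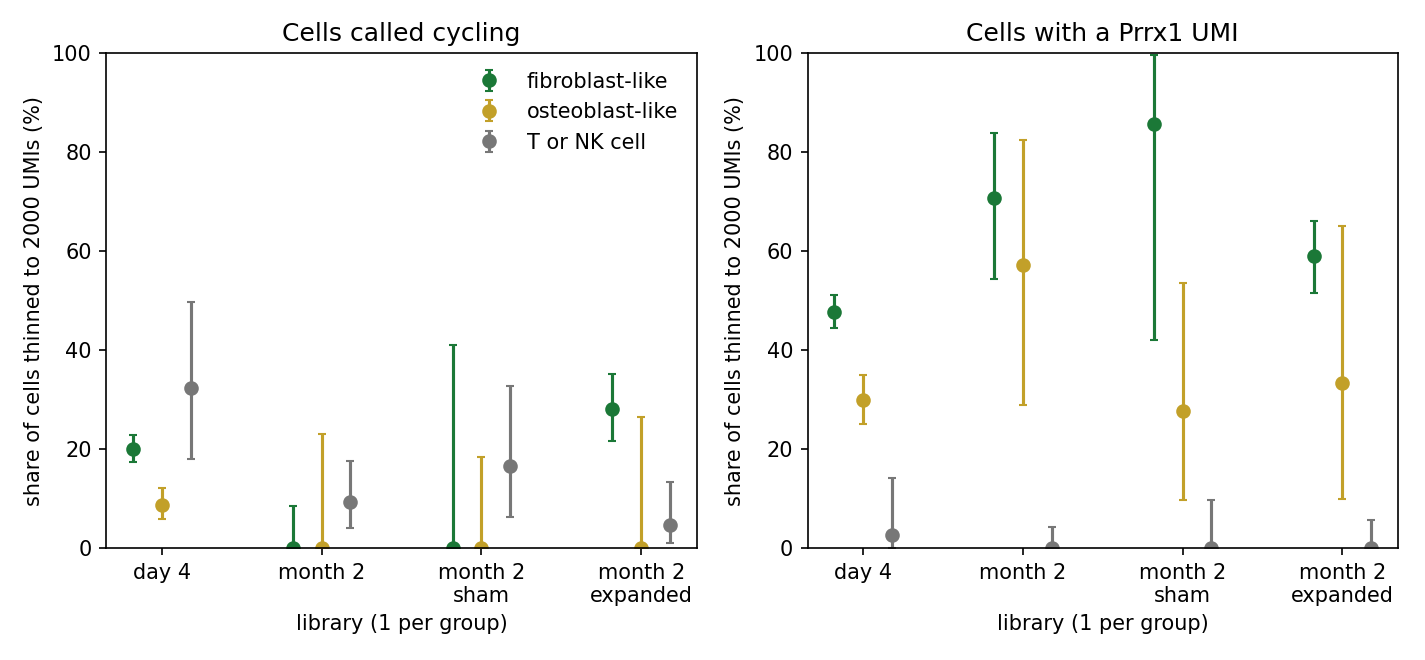
Share of cells (percent, thinned to 2000 UMIs) called cycling (left) and with a Prrx1 UMI (right) among fibroblast-like, osteoblast-like and T or NK cells of 4 libraries, with exact 95% binomial intervals as bars. Cycling fibroblast-like cells stood at 20.0% at day 4 and 28.1% in the expanded library and at 0 in the month 2 and sham libraries. The Prrx1 share of fibroblast-like cells lay far above that of T and NK cells in every library shown, a difference partly built in, as Prrx1 is a marker of the class.

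Prrx1, a transcription factor of suture stem and progenitor cells, was detected in 57.4% of thinned mesenchymal cells of the expanded library and in 44.0% of those of the sham library, a ratio of 1.30 (0.702 to 2.69). At month 2 the share was 67.3%. In fibroblast-like cells alone it was 58.9% in the expanded, 85.7% in the sham (6 of 7 cells) and 70.7% in the month 2 library, an expanded to sham ratio of 0.687 (0.306 to 1.91). No T or NK cell of these 3 libraries had a Prrx1 UMI, at median depths of 3517, 7238.5 and 3607 UMIs against 21951, 31882 and 8855 in mesenchymal cells. Prrx1 is itself a marker that names the fibroblast-like class, so this difference was partly built in. Without thinning the shares were 94.5%, 88.9% and 80.3%. The Prrx1 level in summed mesenchymal counts was 489 counts per 1000000 UMIs (CPM) in the expanded and 216 CPM in the sham library, a log2 ratio of 1.18 (0.96 to 1.41), but within fibroblast-like cells alone it was −0.13 (−0.47 to 0.23). Axin2, a Wnt target that marks suture stem cells, and Six2, a progenitor transcription factor, rested on 1 and 4 sham UMIs, with log2 ratios of 2.84 (0.28 to 8.18) and 2.27 (0.88 to 4.17) in all mesenchymal cells and 0.25 (−2.30 to 5.59) and 0.10 (−1.49 to 2.40) in fibroblast-like cells. Gli1, a Hedgehog target of suture stem cells, had 13 UMIs in the expanded and 3 in the sham library, too few to measure. Itgav, the integrin alpha V subunit used to sort skeletal stem cells, had a log2 ratio of 1.17 (0.70 to 1.67), Ctsk, the protease cathepsin K, of −0.28 (−0.46 to −0.11), and Cd200, a surface glycoprotein of the same sorts, of −2.85 (−3.19 to −2.52). In fibroblast-like cells these 3 stood at 0.57, 0.34 and −2.04.

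Postn, Cxcl5 and Inhba were among the genes higher in expanded mesenchymal cells, and Bglap and Dmp1 among those lower. Osteoblast-like cells supplied 83.9% of the mesenchymal UMIs of the sham library, 35.5% at month 2 and 3.06% of the expanded library, so values for fibroblast-like cells alone stand beside those for all mesenchymal cells. Postn (periostin, a matrix protein of the periosteum, ENSMUSG00000027750, chromosome 3 from 54361109 to 54391037 in mm10) reached 915 CPM against 4.87 CPM, a log2 ratio of 7.55 (6.20 to 9.43), and 4.96 (3.61 to 6.84) in fibroblast-like cells. The neutrophil chemokine Cxcl5 (ENSMUSG00000029371, chromosome 5 from 90759360 to 90761624) reached 404 CPM from 1990 UMIs and had none in the sham library, at least 110.5-fold higher, and at least 4.20 on the log2 scale in fibroblast-like cells. Inhba, which encodes the activin A subunit (ENSMUSG00000041324, chromosome 13 from 16011851 to 16031621), stood at 472 CPM against 4.87 CPM, a log2 ratio of 6.60 (5.24 to 8.48), and at 4.42 in fibroblast-like cells. Il1rl1, the interleukin 33 receptor, was at least 57.3-fold higher with 209 CPM against none. Also among the 12 genes named by the ranking rule were the smooth muscle gene Tagln (5.48), the collagen Col5a3 (6.25), the secreted proteins Ptx3, C1qtnf3 (7.37) and Saa3, the retinoid binding protein Crabp1, and the histones Hist1h1b (8.03) and Hist1h3c, whose reads can be split among their gene family. In fibroblast-like cells alone these 8 genes had log2 ratios from 2.61 (Saa3) to 5.44 (Hist1h1b), 4 of them as lower bounds.

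**Figure D3:**
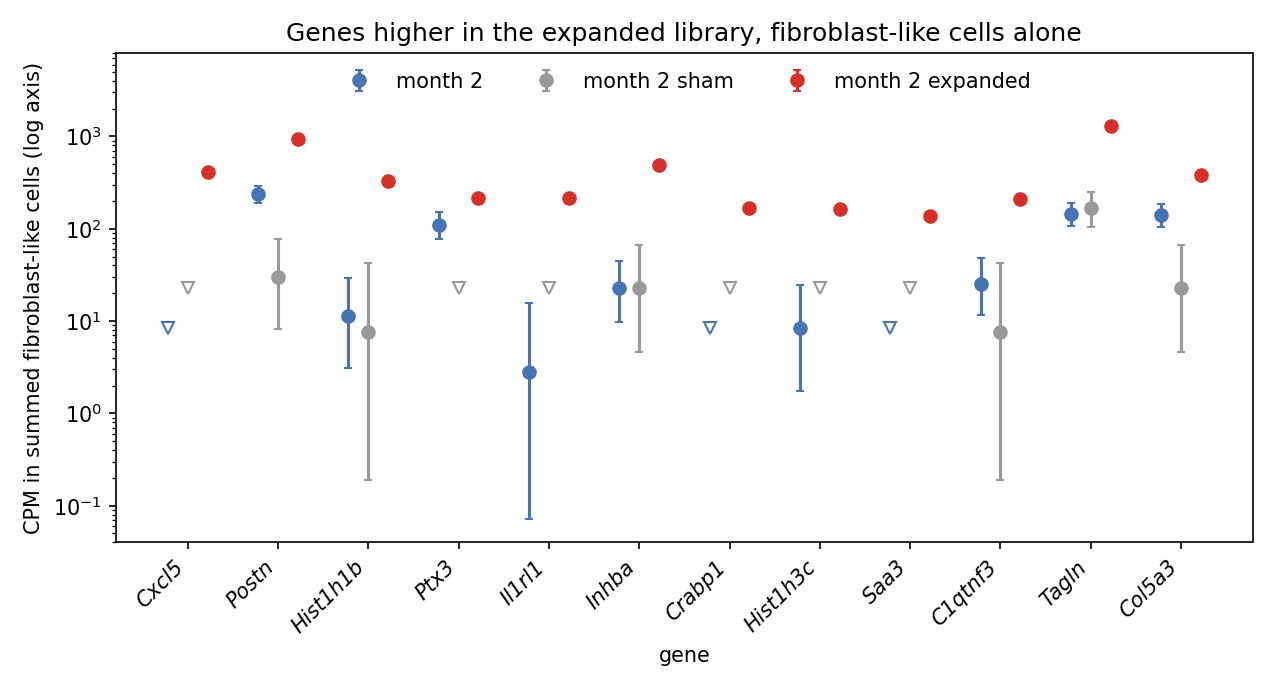
Level of 12 genes (CPM in summed fibroblast-like cells, log axis) in the month 2, sham and expanded libraries, with exact 95% Poisson intervals as bars and open triangles at the level of 3 UMIs where no UMI was seen. All 12 points of the expanded library lie above both references, from 139 CPM for Saa3 to 1286 CPM for Tagln. This was largely built in, as the ranking rule chose these genes for being higher than both in summed mesenchymal counts.

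Among genes lower in the expanded library, Bglap (osteocalcin, the hormone of mature osteoblasts, ENSMUSG00000074483, chromosome 3 from 88383501 to 88384464) stood at 1585 CPM against 99116 CPM, a log2 ratio of −5.97 (−6.00 to −5.93). Its paralog Bglap2 (−5.86), whose reads can be split between near-identical copies, the sialoprotein Ibsp (−4.599) and Ifitm5 (−4.49), an osteoblast membrane protein, went the same way, and Dmp1, of osteocytes, had 0 UMIs against 81, at least 162-fold lower. The others were Gal, Cxcl13, Tbx2, Mlip, Lipc, Car3 and Pla2g5, with log2 ratios from −6.59 to −4.81. In fibroblast-like cells alone Bglap was −1.65 (−3.11 to 0.28), and within the few osteoblast-like cells themselves Bglap stood at 51515 CPM in the expanded, 118139 CPM in the sham and 72262 CPM in the month 2 library. Sp7, the osteoblast transcription factor, had a log2 ratio of −3.53 (−0.42 in fibroblast-like cells), Runx2, which acts before it, of −0.70 (−0.61), and Col1a1, the main bone collagen, of −2.33 (−0.12).

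In all mesenchymal cells the division, collagen, matrix remodelling and inflammatory lists stood high and the osteogenic list low, while in fibroblast-like cells alone the matrix remodelling, inflammatory and osteogenic lists lay within the random range. The median log2 ratio over all 10702 measured genes was 0.86 in all mesenchymal cells and −0.11 in fibroblast-like cells alone, so each list is given with its percentile among 10000 random lists of matched expression. Mitosis genes had a median of 4.16 (percentile 100; Birc5 6.43, Cenpa 5.70 and Top2a 5.70), and 1.57 (percentile 100) in fibroblast-like cells. Of the 35 mitosis genes 16 were entered at the lower bound that 3 UMIs allow, and 24 in fibroblast-like cells. DNA replication genes had 2.58 (percentile 100; Clspn 4.98, Mcm5 4.67) and 0.41 (98.8), and the list used for the cycling call 4.84 and 2.31, both at percentile 100. Mki67, the proliferation antigen, had a log2 ratio of 4.84 (3.48 to 6.72) and Top2a, the DNA topoisomerase of dividing cells, of 5.70 (4.15 to 7.98). Collagens had a median of 2.72 (percentile 100; Col5a3, Col12a1 3.73, Col8a1 3.62) and 0.53 (97.53) in fibroblast-like cells. Matrix remodelling genes (1.74; Loxl2 5.05, Tnn 4.89), inflammatory cytokines (2.26; Cxcl2 4.6, Vcam1 4.24) and hypoxia and glycolysis genes (2.17; Eno1 3.15, Vegfa 2.71) all lay at percentile 100, with fibroblast-like medians of 0.15 (percentile 85.1), 0.54 (97.3) and 0.97 (percentile 99.97). Osteoclast regulators had 2.64 (99.98; the osteoclast cytokine Tnfsf11 3.75 and its decoy receptor Tnfrsf11b 2.64), vascular and nerve growth factors 2.54 (100) and senescence genes 2.26 (99.97), against 0.46, 0.07 and 0.15 in fibroblast-like cells. Osteogenic genes stood at −2.99 (percentile 0), and at −0.54 (8.10) in fibroblast-like cells.

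Stem and progenitor genes had a median of 1.11 (percentile 89.2; Grem1 4.37, Thy1 2.43, Cd200 −2.85) and −0.14 in fibroblast-like cells. Wnt genes had 1.15 (87.0) and −0.54, Hedgehog genes 1.34 (87.2) and −0.58, FGF and IGF genes 1.03 (82.1) and −0.60, and YAP and TAZ targets 0.94 (70.5) and −0.11. Chondrogenic genes had 1.81 (98.7) and −0.01. BMP and TGF-beta genes stood at 0.56 (10.9), with Inhba and Grem1 far above and Bmp3 (−4.05) far below, and at −0.78 (percentile 0.025) in fibroblast-like cells. In fibroblast-like cells a gene without a sham UMI was entered at 22.7 CPM, the level of 3 sham UMIs. Below that level in the expanded library it counted as negative, though it carries no direction. Negative fibroblast-like medians against sham, those of osteogenic genes included, are therefore uncertain in size and sign. Interferon genes had 0.90 (57.8) and −0.20, oxidative phosphorylation genes 0.63 (56.7) and 0.46, genes of dissociation stress −0.11 (0.47) and −0.45, and adipogenic genes −0.23 (1.40) and −1.33.

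**Figure D4:**
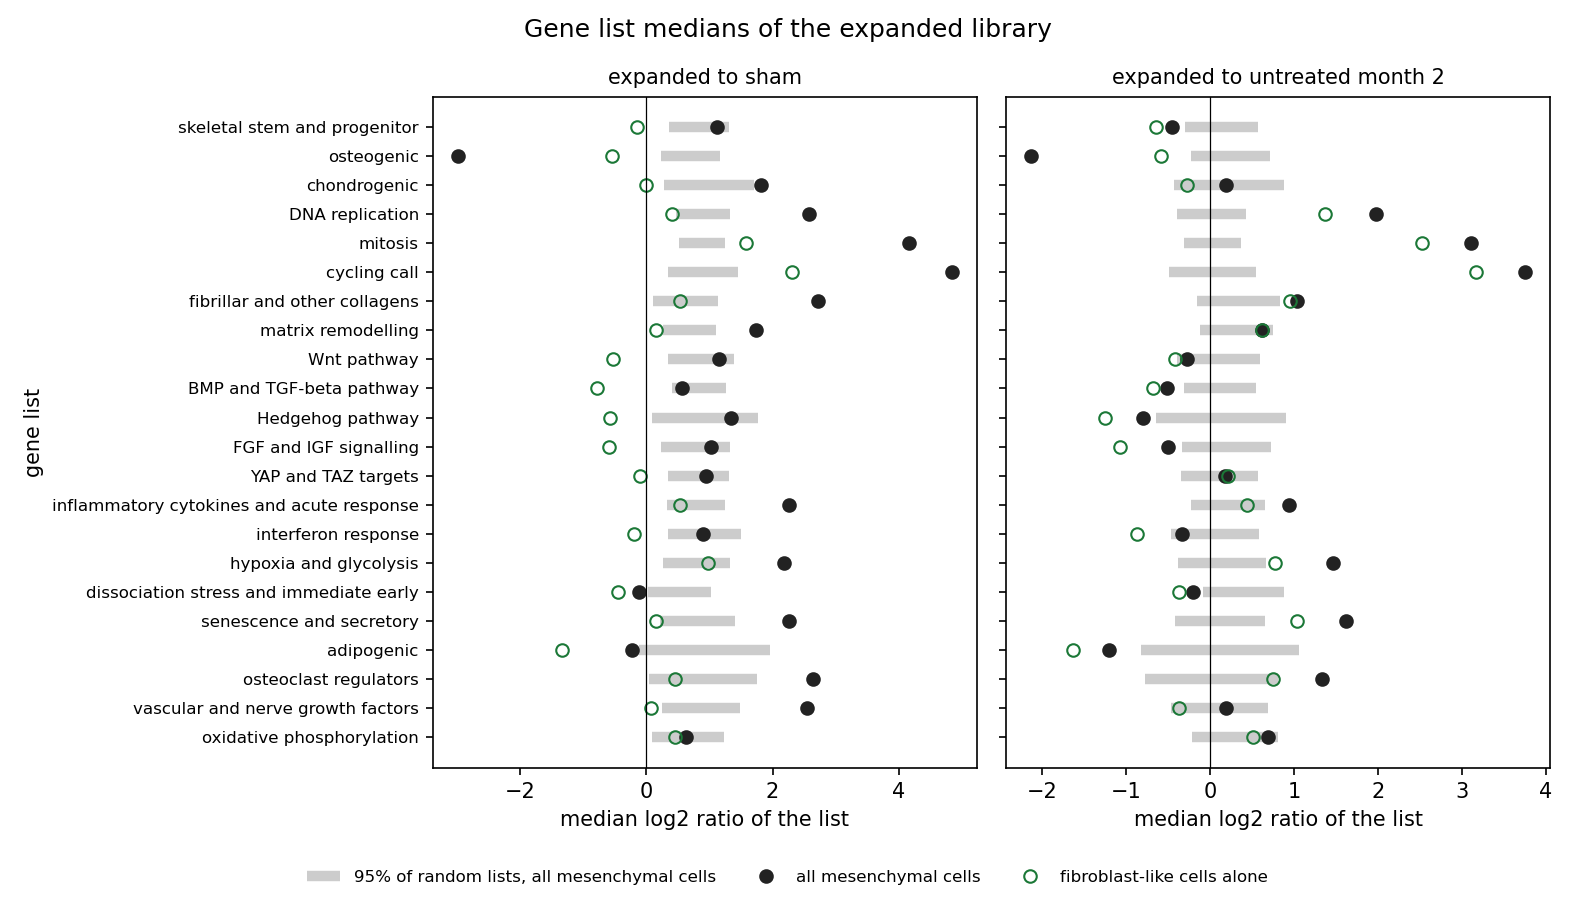
Median log2 ratio of 22 gene lists (1 per line) for the expanded against the sham library (left) and against the untreated month 2 library (right), for all mesenchymal cells (filled) and fibroblast-like cells alone (open), with grey bars for the central 95% of matched random lists in all mesenchymal cells. Mitosis genes stood at 4.16 and 3.11 in all mesenchymal cells, to the right of the random range in both panels, and at 1.57 and 2.52 in fibroblast-like cells.

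Set beside the untreated month 2 library, the expanded library again held more cycling mesenchymal cells, at least 4.84-fold, all of them fibroblast-like. Tnn (tenascin W, a matrix protein of periosteum and sutures, ENSMUSG00000026725, chromosome 1 from 160085029 to 160153580) reached 615 CPM from none, at least 113-fold higher, and at least 6.22 on the log2 scale in fibroblast-like cells. Cxcl5 was at least 73.8-fold higher, Il1rl1 had a log2 ratio of 6.85, Inhba of 5.02 (4.04 to 6.23), Prg4 (lubricin) of 5.89, Fabp5 of 4.45, Hist1h1b of 5.12 and the mitotic gene Prc1 of 6.19. Actg2, Crabp1, Saa3 and the kinetochore gene Cenpf had no UMI at month 2. Lower were Chad (chondroadherin, no UMI against 53), the Wnt antagonist Sfrp4 (−5.49, −6.08 in fibroblast-like cells), Pi16 (−4.81, −5.40) and the matrix genes Tnxb (−4.85), Col6a5 (−5.46) and Fbln7 (−4.83), together with Myoc, Nppc, Car3, Pla2g5, Bglap and Bglap2. The mitosis list had a median of 3.11 (percentile 100, 2.52 in fibroblast-like cells), DNA replication 1.98 (1.38), collagens 1.03 (percentile 99.9, 0.95) and hypoxia and glycolysis 1.46 (0.78). Osteogenic genes stood at −2.13 (percentile 0, −0.58), FGF and IGF genes at −0.50 (−1.07), Hedgehog genes at −0.80 (−1.25) and adipogenic genes at −1.20. Among the genes fixed beforehand, Mki67 stood at 4.26 (2.90 to 6.14), Top2a at 3.90 and Postn at 2.58 (2.27 to 2.91), against −0.15 for Prrx1 (−0.54 in fibroblast-like cells), 0.26 for Axin2, −0.77 for Six2, 0.43 for Ctsk, 0.70 for Itgav, −1.91 for Cd200, −1.22 for Runx2 and −2.91 for Sp7. Col1a1 was −1.42 in all mesenchymal cells and 1.94 in fibroblast-like cells.

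The sham library against the untreated month 2 library showed how far 2 libraries of the same age without expansion stood apart. Osteoblast-like cells were 2.42-fold more frequent after the sham operation (1.16 to 5.07) and fibroblast-like cells less frequent, at a ratio of 0.430 (0.185 to 0.890), while the mesenchymal share was alike (0.951, 0.581 to 1.52). The higher genes included Cthrc1 at a log2 ratio of 2.07 (1.80 to 2.36; 2.23 in fibroblast-like cells), the metalloproteinase inhibitor Timp1 at 1.77 (2.52) and the monocyte chemokine Ccl7 at 1.28 (3.29). Fkbp11, Ssr4, Kdelr2, Tmsb10, Serf1, Ppic, Sec61b and Ndufa4l2 had log2 ratios from 1.11 to 1.81. The lower genes included the growth factor carrier Igfbp5 (−4.17, −2.25 in fibroblast-like cells), Col14a1 (−4.01), the cadherin Fat4 (−5.08) and Shisa3 (−6.64), beside Chad, Col6a5, Itga8, Egfl6, Nppc, Slc7a11 and Fndc5 with no UMI in the sham library and Specc1l with 1. Postn was −4.97 (−6.88 to −3.56), Prrx1 −1.33, Six2 −3.04, Ctsk 0.72, Cd200 0.94, Runx2 −0.51, Sp7 0.61, Bglap 1.95, Col1a1 0.91 and Itgav −0.47, and Axin2, Gli1, Mki67 and Top2a had under 20 UMIs in both libraries together. The median of all genes was −0.71. Osteogenic genes had a median of 0.87 (percentile 100) and FGF and IGF genes of −1.97 (percentile 0), collagens −1.57 (percentile 0), inflammatory genes −1.45 (0.16) and growth factors −2.17 (0.02), and in fibroblast-like cells these 5 stood at −0.24, −0.78, 0.29, 0.37 and −0.44. No gene of the cycling call had enough UMIs to be measured.

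The age course asked how suture cells change from the newborn to the old mouse. At day 4 49.6% of cells had Xist and no Y-linked transcript, against at most 4 cells in any later library. By these transcripts the day 4 library held both sexes, so no day 4 difference can be told apart from one of sex. Mesenchymal cells held 48.6% of the day 4 library and 0.18% of that of month 14 (0.0821% to 0.341%), a ratio of 271 (142 to 594) that was 88.4 when cells were classed one by one by marker score and 143 (89.3 to 247) when the unnamed Cxcl12 stromal cluster was counted as mesenchymal, with 1.86% at month 2 and 0.113% at month 4. The day 4 to month 2 ratio was 26.2 (20.3 to 34.4). Of cells outside blood and immune classes, mesenchymal cells formed 73.9% at day 4, 21.0% at month 2, 24.1% at month 4 and 42.9% at month 14, a day 4 to month 14 ratio of 1.73 (0.906 to 3.78). B cells held 7.75% at day 4 and 16.0%, 16.6% and 23.2% at the later ages, T and NK cells held 1.49% at day 4 and 5.03% at month 14, and plasma cells numbered 0, 1, 16 and 21 along the course. At day 4 205 of 1226 thinned mesenchymal cells were cycling (16.7%, 14.7% to 18.9%), 20.0% of fibroblast-like and 8.73% of osteoblast-like cells, at least 3.07-fold more than at month 2. The class was made of other clusters at the 2 ages: at day 4 569 fibroblast-like cells were in cluster 12 (median 2012 UMIs, 13.7% mitochondrial), 521 in cluster 14 and 73 in the Mgp-led cluster 27, which held 40 of the 45 of month 2. Within cluster 27 6 of 69 thinned day 4 cells were cycling (8.70%, 3.26% to 18.0%) and none of 37 at month 2. At month 14 it was 1 of 7 cells, a day 4 to month 14 ratio of 1.17 (0.208 to 46.5), and at month 4 0 of 7. Unthinned, 39.3% of day 4 cells were called. T and NK cells were called at 32.4% at day 4 (12 of 37 cells, median depth 7630 UMIs against 9625.5 in mesenchymal cells), so the day 4 share did not stand above that class. Prrx1 was detected in 42.6% of thinned mesenchymal cells at day 4, 67.3% at month 2, 4 of 7 cells at month 4 and 2 of 7 at month 14, and in 2.70% of day 4 T and NK cells. Within cluster 27 it was 36.2% at day 4 (25.0% to 48.7%) and 73.0% at month 2 (55.9% to 86.2%). The day 4 to month 2 ratio in all mesenchymal cells was 0.633 (0.453 to 0.909) and that of day 4 to month 14 was 1.49 (0.410 to 12.3). Thinning left out 337 day 4 cells.

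Day 4 mesenchymal cells had higher division genes and lower interferon and inflammatory genes than those of month 2, while the osteogenic and collagen lists lay within the random range. Ibsp (bone sialoprotein, ENSMUSG00000029306, chromosome 5 from 104299171 to 104311469) stood at 9888 CPM against 459 CPM, a log2 ratio of 4.43 (4.25 to 4.61), and within osteoblast-like cells at 30556 CPM against 966 CPM, while Bglap was −3.53 (−3.55 to −3.50) in all mesenchymal cells and stood at 6648 CPM against 72262 CPM in osteoblast-like cells. Panx3, a channel of osteoblasts and hypertrophic cartilage, and Tnn (987 CPM) had no UMI at month 2, the latter at least 181-fold higher at day 4. Cenpf, Hist1h2ae (6.22), the microtubule regulator Stmn1 (4.57) and the matrix ligand Npnt (4.32) were also higher, and Mki67 (3.66), Top2a (3.59) and Postn (3.02) as well. The lower genes held the interferon-inducible Ifi203 (−8.09), Ifi205 (−8.88) and Slfn5 (−5.80), and Myoc, Col6a5, Fgl2 (−5.75), Smoc1 and the iron carrier Trf (−5.88). Other named genes differed alike in blood cells of the day 4 library: Stfa1, Cstdc4, Cstdc5, Xist and Tsix were higher there in B cells too (Stfa1 at 262 CPM in B cells, 283 CPM in mesenchymal cells and 29949 CPM in myeloid progenitors), and Rnasek (−7.28), Atp6v0c (−5.61) and B3gnt2 (−6.58) were lower. Tnn, Ibsp, Npnt and Panx3 had 35.1 CPM, 132 CPM, 13.8 CPM and 5.43 CPM in day 4 B cells and no UMI in those of month 2, and Hist1h2ae was higher in day 4 B cells too (1.38, 1.29 to 1.48), as was Stmn1 (0.74). Ifi203 (−2.85), Slfn5 (−3.07), Fgl2 (−2.23) and Trf (−1.84) were lower in day 4 myeloid progenitors as well, and Ifi203 (−1.12) and Trf (−1.49) also in B cells. Ttr (−7.38), the leading gene of a cluster with 43 month 2 cells and no day 4 cell, was lower in B cells as well.

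By lists, mitosis (median 2.46, percentile 100; 2.22 in fibroblast-like cells), DNA replication (1.5, 100) and the cycling genes (2.88, 100) were higher at day 4, with oxidative phosphorylation (0.79, 98.8). Chondrogenic genes had 1.20 (99.97; Acan 2.15, Comp −5.85) but −0.37 in fibroblast-like cells. Interferon genes were lower with a median of −2.26 (percentile 0; Gbp2 −4.29, Oasl2 −3.33), and so were inflammatory genes at −1.32 (0; Il33 −4.03, Ccl2 −2.99), vascular and nerve growth factors at −1.13 (0.11), BMP and TGF-beta genes at −0.86 (0.06), FGF and IGF genes at −0.74 (0.42; Igf2 −4.03) and stem and progenitor genes at −0.73 (0.90). Osteogenic genes stood at 0.25 (67.6), and at 0.84 (99.99) in fibroblast-like cells, and collagens at −0.02 (26.5). Gli1 had 337 UMIs at day 4 and none at month 2, at least 4.18-fold higher. Prrx1 was −0.84 (−1.01 to −0.67), Six2 −1.06, Axin2 1.06 (−0.32 to 2.95), Ctsk 0.30, Itgav 0.10, Cd200 0.03, Runx2 −0.07 and Sp7 0.09, and Col1a1 was −0.27 in all mesenchymal and 2.53 in fibroblast-like cells. The median of all genes was −0.18.

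The month 4 and month 14 values rest on 7 and 9 mesenchymal cells. At month 4 Bglap3 (3.98), the vitamin D receptor Vdr (2.94), Ptprz1 (2.76) and Tgfb1 (2.06) were higher than at month 2, with Ddit4, Dio2, Cdc42ep3, Sorbs2, Nrp2, Itga10, Fxyd6 and Insc at log2 ratios from 1.84 to 3.27. Igf2 (−5.03), Peg3 (−5.79), Fn1 (−3.13), Ccl2 (−4.22) and Hsph1 (−3.41) were lower, and Ifi27l2a, Ifi203, Postn, Dpt, Clec3b, Ccl7 and Ttr had no UMI. At month 14 Spp1 (2.53), Ibsp (1.78), Col1a1 (1.48) and Col11a2 (1.47) were higher, as were Slitrk6, Pqlc1, Lrp4, Neat1, Tnc, Lifr and Sbno2. Mki67 was higher too (5.19), from 23 UMIs that all came from the 3 fibroblast-like cells, which held 11005 UMIs in all. As those 3 cells had no UMI of Col3a1, a marker of the class, their naming is uncertain. Mgp, the calcification inhibitor, had no UMI against 3701, at least 194-fold lower. All 3 fibroblast-like cells of month 14 fell in cluster 12, led by Col16a1, while 40 of the 45 of month 2 fell in cluster 27, which Mgp leads, so the class was not made of the same clusters at the 2 ages. Col3a1, itself a marker of the class, Apoe, Ecrg4, Plpp3, Ogn, H19, Igfbp6, Igf1 and Fgl2 also had none, and Igfbp5 (−6.57) and Fxyd5 (−6.29) had 5 and 1. Osteoblast-like cells supplied 60.3% and 87.2% of the mesenchymal UMIs at month 4 and month 14, and the medians of all genes were −0.20 and −0.65. Osteogenic genes had medians of 0.60 (percentile 99.99) and 0.85 (100), collagens of −0.72 (0.05) and −1.72 (0), and inflammatory genes of −1.78 (0) and −1.87 (0.02). Bglap stood at 0.38 and 1.01, Prrx1 at −0.18 (−0.57 to 0.20) and −1.46 (−2.26 to −0.76), and Cd200 at 1.74 and 1.51.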

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

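The test of the day 4 gene annotation was written before its result was seen, and the other tests in this part were chosen only after the results were seen.

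The share of fibroblast-like cells stood at 8.44 times the sham share in the expanded library (4.35 to 18.7). A lower yield of blood cells alone would raise all other classes alike, but the osteoblast-like ratio was 0.271 (0.119 to 0.594), and against month 2 the endothelial ratio was 0.847 (0.508 to 1.41) beside 3.63 (2.61 to 5.14) for fibroblast-like cells. The endothelial ratio to the sham library, 13.4 (2.24 to 545), went with that explanation but rests on 1 sham cell. Neuron or astrocyte cells also went with it, 22 against 0 sham cells (at least 2.98, lower end 2.22). Schwann or glia cells numbered 10 against 0 (lower end 0.910). Against month 2 these classes stood at 0.738 and 0.623. Epithelial cells stood at 7.85 times month 2 (1.09 to 344, 9 cells against 1). Of neuron or astrocyte cells, 19 of 22 in the expanded library were in cluster 44, led by S100a5. At month 2 18 of 26 were in cluster 46, led by Snhg11, and neither cluster held cells of both. The unnamed Ttr cluster, set aside as choroid plexus, held 43 cells at month 2 and 0 in the expanded library. Cells from outside the suture thus differed between those libraries. Whether dissected tissue also shaped the fibroblast-like share stays open. Carry-over of meningeal cells rich in Ptgds was argued against by Ptgds at 8.37 CPM in expanded fibroblast-like cells (5.98 to 11.4) and by no UMI of Slc6a13 or Slc22a6. These genes were as low at month 2 (Ptgds 11.3 CPM, the others 0), so they cannot speak for meningeal cells that lack them. Slc47a1 (24.3 CPM against 223 CPM), Foxd1 (149 against 310.5), Cldn11 (17.6 against 53.6), Foxc2 (29.3 against 53.6) and Aldh1a2 (2.09 against 8.47) stood below month 2, the last 2 with overlapping intervals. Crabp2 stood at 44.8 CPM (39.0 to 51.2) against 28.2 CPM (13.5 to 51.9). In the sham library Slc47a1, Foxd1, Cldn11 and Aldh1a2 were also higher than in the expanded one. Foxc2 (7.56 CPM, 1 UMI), Crabp2 (30.2 CPM, 4 UMIs) and Ptgds (no UMI) were lower there. As month 2 and sham cells may be meningeal in part, these levels leave other meningeal cells open. A difference in how well each library released osteoblast-like and fibroblast-like cells stays open, as does a response to expansion, which 1 library per group did not let be tested.

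The cycling fibroblast-like cells of the expanded library were set against 3 technical explanations. Free RNA of dividing myeloid progenitors and B cells was argued against, since cycling transcripts per blood progenitor marker UMI stood 114-fold (96.5 to 135) above those of blood progenitors. These markers are not those of neutrophils, of which 21.6% were called cycling in the expanded library. Free RNA of dividing neutrophils was thus not tested. More cycling calls in all classes were argued against by the ratios to month 2 among classes with 50 cells or more in both libraries. The highest was 1.65 (1.32 to 2.07, B cells) beside at least 4.84. Against sham this explanation stayed open, as neutrophils reached 1.77 (1.42 to 2.23) and the fewer dendritic cells 1.87 (0.698 to 6.26) beside at least 2.20. Doublets with dividing blood cells were not excluded as a contributor: cycling cells carried 43.8 CPM of blood progenitor markers and other fibroblast-like cells 30.3 CPM, a ratio of 1.44 (1.05 to 1.98), which that explanation predicts. A further test, added after that one, put the marker level of the cycling cells at 0.311% of that of the same blood classes (0.243% to 0.392%). This lies far below the share that doublets with myeloid progenitors or B cells as the whole source would need. Doublets with dividing neutrophils or macrophages were not tested in this way. The neutrophil transcripts S100a8 (72.3 against 1029 CPM) and S100a9 (141 against 1487 CPM) stood lower in cycling than in other fibroblast-like cells. That is the reverse of what neutrophil doublets as the source would bring. No such values were read for macrophages. Division of fibroblast-like cells after expansion therefore stays a hypothesis, found and tested on the same cells.

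In the day 4 library 23 genes stood at least 4-fold lower than in the other 5 libraries in all of 4 blood classes, a signal outside the comparisons made, while none stood so in any other library compared with the 4 others from month 2 on. Of these genes 60.9% (14 of 23, 38.5% to 80.3%) overlap, on the same strand, a gene listed only in the day 4 file, against 2.5% of 9562 other expressed genes, which is consistent with reads lost to a different gene annotation. Of the genes named as lower at day 4, Rnasek and B3gnt2 have such an overlap and Atp6v0c, also among the 23, has none. The other genes named as lower were not among the 23, so no overlap was read for them. Loss to the annotation was therefore not tested for those genes. The genes without an overlap, and 65 genes that stood higher at day 4 in the 4 classes, were not accounted for by this test, and age stays untested as an explanation for them.

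Of the kept day 4 cells 1594 (49.6%) had Xist and no Y-linked transcript, beside 678 with a Y-linked transcript only and 210 with both, in a library labelled male. In the other libraries 0 to 4 cells had Xist only. By these transcripts the day 4 library held cells of both sexes, so its contrasts with later ages join age and sex. The month 4 and month 14 libraries shared 76 barcodes, against at most 9 for any other pair of libraries, with median depths of 32916 UMIs in the larger and 966 UMIs in the smaller of each pair.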

How the results depend on the processing

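The alternatives for osteoclasts and those with the Cxcl12 cluster, without the shared barcodes, with month 2 as the reference and with fibroblast-like cells alone for the cycling and Prrx1 ratios were chosen only after the results were seen. No paired analysis was possible because each group had 1 library. A change of direction was counted only where the first value stood clear of no change, by an interval without 1 (or 0 on the log2 scale) or a list median outside the random range. Of the recomputed ratios of shares 55 stayed within their interval, 7 moved and 1 changed direction; the counts were 407, 105 and 7 for list medians and 858, 282 and 17 for gene ratios.

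As a share of cells outside blood and immune classes, the expanded to sham ratio of mesenchymal cells was 0.816 and the day 4 to month 14 ratio 1.73, and by marker score the latter was 88.4 and with the Cxcl12 cluster 143. The expanded to sham ratio of cycling cells was 1.69 with thinning to 1000 UMIs, 1.71 without thinning and 1.61 with 3 genes, and the Prrx1 ratio was 0.687 in fibroblast-like cells. With median-of-ratios scaling, which shifted expanded to sham log2 ratios by 0.85, the medians were −3.83 for osteogenic genes, 3.32 for mitosis and 1.87 for collagens. With 100 UMIs the osteogenic median was −2.43 and with doublets kept −2.39. As means over cells, mitosis stood at 3.097 and collagens at 1.70, and mitosis against month 2 at 2.59. The osteoclast ratio to month 2 was 2.53 with doublets kept, where the cluster so named had a median of 1734 UMIs against 25782.5. For all of these the cause was not tested.

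In fibroblast-like cells alone, which lack the osteoblast-like cells by construction, expanded to sham medians were −0.54 (osteogenic), 1.57 (mitosis), 0.53 (collagens) and −0.0137 (chondrogenic, reversed), and mitosis against month 2 was 2.52. Genes without a UMI in 1 library stayed in these medians at bounds that can carry no direction. Reversed in fibroblast-like cells were also the sham to month 2 medians of osteogenic (−0.24), collagen (0.29) and inflammatory genes (0.37) and the day 4 chondrogenic median (−0.37). So were Prrx1 (−0.13) and Ctsk (0.34) against sham, Sp7 (0.00069) and Col1a1 (1.94) of the expanded library against month 2, Sec61b (−0.24) and Bglap (−1.94) of the sham library, Bglap (0.73) and Col1a1 (2.53) at day 4, and Nrp2 (−2.92), Bglap (−1.20) and Col1a1 (−0.40) at month 4. As means over cells, Six2 (−0.22) and Ctsk (0.0448) against sham, Runx2 of the sham library (0.87), Bglap (−0.65) and Col1a1 (−0.42) at month 4 and the dissociation median against month 2 (0.0773) reversed. Runx2 of the sham library (0.19, median-of-ratios) and its chondrogenic median (0.40, 100 UMIs) reversed too. For these single values the cause was not tested.

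No value was given by fibroblast-like cells alone for the expanded to sham cycling ratio (0 of 7 sham cells, fewer than the floor resolves), for Ibsp expanded to sham, or for Six2, Ctsk, Bglap and Postn at month 14. Nor was one given by median-of-ratios scaling for Six2 at month 14, by the limit of 10% mitochondrial UMIs for the day 4 to month 14 cycling and Prrx1 ratios (0 of 3 cells), or by 100 UMIs for the sham to month 2 medians of DNA replication, mitosis and osteoclast regulators. The sham library gave 9 fibroblast-like cells and months 4 and 14 gave 7 and 9 mesenchymal cells, the 3 fibroblast-like of month 14 at a median of 2978 UMIs against 7492 at month 2.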

Other observations

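All values and groupings in this part were chosen only after the results were seen. Within the expanded library the 52 cycling fibroblast-like cells (median 27465 UMIs) differed from the 133 others (21597 UMIs). Mgp, the calcification inhibitor, stood at 1022 CPM in cycling and 3144 CPM in other cells, a ratio of 0.325 (0.308 to 0.342). Il1rl1, the interleukin 33 receptor, was higher in cycling cells at 319 CPM against 162 CPM (ratio 1.96, 1.74 to 2.22), as were Inhba (1.60, 1.47 to 1.74) and Tnn (1.42). Prrx1 stood at 517 CPM against 488 CPM (1.06, 0.972 to 1.15) and Postn at a ratio of 0.906. Col1a1 (0.719), Ctsk (0.638) and Runx2 (0.743) were lower in cycling cells, and Pi16 had no UMI against 24 in the others. S100a8, a neutrophil transcript, stood at 72.3 CPM in cycling and 1029 CPM in other cells.

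A macrophage cluster led by Ccl8 and complement C1q genes held 144 kept cells of the expanded, 14 of the sham and 41 of the month 2 library. In it Spp1 (osteopontin, a matrix and cytokine protein) stood at 1602 CPM in the expanded library, 19.9 CPM in the sham library (3 UMIs) and 11.7 CPM at month 2 (2 UMIs). Arg1, the arginase of tissue repair macrophages, stood at 437 CPM, 6.64 CPM (1 UMI) and 0. The sham and month 2 values of both genes lie at or under the level of 3 UMIs, 19.9 CPM and 17.5 CPM. Gpnmb, a glycoprotein of lysosomes, and Vegfa, the vascular growth factor, were at least 8.76-fold and 6.68-fold above the sham library, where both had no UMI. The scavenger receptor Stab1 (587, 86.4 and 291 CPM), Dab2 (1414, 359 and 845 CPM) and the folate receptor Folr2 (288, 53.1 and 157 CPM) were higher as well. Vcam1 (367, 3175 and 1726 CPM), Il1b (363, 3023 and 600.5 CPM) and Axl (80.7, 638 and 367 CPM) were lower.

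The surface profile used to sort mouse skeletal stem cells (Itgav, Cd200 and no Thy1, Enpep or Eng), read from transcripts of thinned mesenchymal cells, was met by 23 of 1226 cells at day 4 (1.88%, 1.19% to 2.80%). It was met by 0 of 55 cells at month 2, 0 of 25 in the sham library, 0 of 197 in the expanded library and 0 of 7 at month 4 and at month 14. These counts read the detection of transcripts at 2000 UMIs, where Itgav or Cd200 can be missed, so they set no limit on the share of such cells. No neutrophil of any library met it.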
